A study of Homo sapiens with 21 samples.

How the data were processed

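RNA of HL-60 cells, a human promyelocytic leukaemia line, was measured on 21 oligonucleotide arrays (Affymetrix HuGeneFL). In one arm the cells received all-trans retinoic acid (ATRA) at 1 uM, in the other the phorbol ester PMA at 10 nM. The ATRA arm holds 9 arrays, of which 3 are untreated, and the PMA arm holds 12, of which 5 are untreated. Arrays were grouped by their titles. The title of array 0 of ATRA 5d gives 5 days and its description gives 3 days, so the fits were repeated with it moved to 3d and with it left out. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

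The deposited values are probe set intensity values on a linear scale, with negative values, as the numbers themselves show. The software and scaling that the authors used are not given in the sources used here. The 75th percentile of the deposited intensity lay between 1227.6 and 1642.3 on 16 arrays and between 146.4 and 196 on 5 arrays (ATRA 5d array 1, PMA 0hr control array 0, PMA 4hr array 1, PMA 12hr array 0 and PMA 24hr array 1), so the arrays are not comparable as deposited. Each array was quantile normalized, floored at 100 and put on a log2 scale. The floor of 100 had been fixed for values near scanner scale. The mean distribution of the 5 lower arrays was therefore taken as the target, a choice made after the scales were seen and before any test. The plan written beforehand named quantile normalization over the 21 arrays with this floor. Read literally, that is a target averaged over all 21 arrays, which was run as an alternative.

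Of 7129 probe sets, 5709 have 1 gene symbol in the platform annotation, 321 have several and 1099 have none. A total of 58 control probe sets were left out of the tests. The probe set with the highest mean stood for a gene, and probe sets without a single symbol were tested under their own ID. A gene was kept if it lay above the floor on at least 2 arrays, which left 3301, of which 2702 have 1 symbol. No genome was used, so no coordinates are given. The number of arrays limits the precision.

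Groups were compared with limma (version 3.58.1, R 4.3.3) in 1 fit with 8 group means, which pools the spread over all arrays. All untreated arrays of an arm formed 1 control group, and each treatment contrast stayed within its arm. The comparison of PMA-arm controls by culture time used 10 group means. The Benjamini-Hochberg adjusted p threshold was 0.05 per comparison, and the limma and camera tests were two-sided. The fit had 13 residual degrees of freedom. Where every array of a group lies at the floor its spread is 0, so the standard errors of such genes are too small and their p-values too low. Their fold is a bound, written "at least": the other group's mean over all its arrays against the floor. Where arrays of 1 side lie partly at the floor, the fold is on the floored scale and understates the change.

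A total of 28 gene lists were fixed before the data were examined, as were the groups, the comparisons, the tests, the planned settings and the rule for named genes. Of these lists, 25 had at least 3 measured members: study signature, neutrophil maturation, primary granule, monocyte-macrophage, myeloid transcription factors, progenitor, NF-kB and cytokines, immediate early, retinoid response, interferon response, S phase, G2 and mitosis, G1 and cell cycle exit, nucleolar and MYC, ribosomal proteins, lysosome, cholesterol synthesis, apoptosis, MHC class I, MHC class II, glycolysis, adhesion and cytoskeleton, and markers of T cells, fibroblasts and epithelium. Markers of B cells, erythroid cells and megakaryocytes had fewer. Lists were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also counted after an adjustment over the list alone. Named genes were the 10 that rose most and the 8 that fell most in each main comparison with every treated array beyond every control array, the 4 in each direction in the other comparisons, up to 4 members per list, and a fixed set of markers. CYP26A1, in that set, was not among the genes tested. The contrasts of 2 times within an arm were not among the comparisons fixed then. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

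On simulated data built from the real control means and spreads of 3301 genes, with 100 genes well above the floor changed at each size, 2-fold changes were recovered at 78% for ATRA over all times, 60% for ATRA 24hr, 87% for PMA over all times, 65% for PMA 4hr and 79% for PMA 24hr. For 4-fold changes the shares were 99%, 96%, 100%, 96% and 99%. False calls among 3071 unchanged genes numbered 10, 6, 14, 13 and 16. In each of these comparisons camera called a shifted set of 30 genes and 0 of 50 sets of unchanged genes. The simulated genes were drawn independently, with no correlation between genes and no classes of arrays by RNA bias or mismatch signal. The false calls of genes and sets on the real arrays can therefore be more numerous.

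The alternatives tried were the deposited values without scaling, a common 75th percentile, floors of 20 and 200, no filter and a filter of 11 arrays, the mean of probe sets, each arm alone, a trend with robust moderation, array weights (whose estimation stopped before convergence), a replicate block, other choices of controls and each array left out. The literal quantile target, which follows the wording of the plan, was also run. Added after seeing the data was the GAPDH 3'/5' ratio as a covariate. So were blocks for the deposited scale and for 9 arrays with bright mismatch controls (a TrpnX-M control signal under -500). Fits without those 9 arrays and without the 5 arrays of lower scale were added too. A last one left out the 5 arrays whose RNA was 3'-biased (log2 of the GAPDH 3' over 5' control signal above 0.9).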

Results

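HL-60 cells were profiled during differentiation with ATRA, the ligand of retinoic acid receptors, and with PMA, an activator of protein kinase C. The ATRA groups held 2 arrays each at 24hr, 3d and 5d, against 3 untreated arrays of the arm. The PMA groups held 2 arrays at 4hr, 2 at 12hr and 3 at 24hr, against 5 untreated arrays. Untreated arrays came from 0hr and 5d in the ATRA arm and from 0hr and 24hr in the PMA arm. ATRA 24hr, ATRA 3d, PMA 4hr and PMA 12hr have no untreated array of their own culture time. Compound and culture time are therefore partly mixed in these comparisons and in those over all times. Correlations between arrays of a group ranged from 0.920 to 0.980. The RNA was 3'-biased on 5 arrays, both ATRA-arm 0hr controls, PMA-arm 0hr controls 0 and 1, and ATRA 24hr array 1, where the GAPDH 3'/5' log2 ratio reached 3.13. The 3' control signal of TFRC, the transferrin receptor, had a mean of 42.5 on the 4 untreated arrays with 3' bias and 1214 on the other 4. GAPDH itself moved by -0.06 (SE 0.08) with ATRA and 0.10 (SE 0.07) with PMA on the log2 scale, and ACTB by 0.06 (SE 0.11) and 0.09 (SE 0.09), none of which passed the test. With a common 75th percentile ACTB was at -0.01 with ATRA. In the values as deposited, where the median of all genes was at -0.21 with ATRA and -0.46 with PMA, ACTB was at -0.44 and -0.67 and GAPDH at -0.53 and -0.60. GAPDH and ACTB are widely used reference genes.

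**Figure D1:**
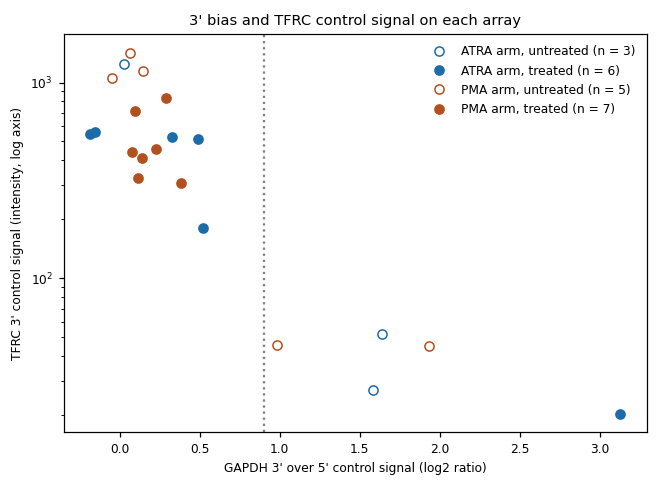
TFRC 3' control signal (intensity, vertical log axis) against the log2 ratio of the GAPDH 3' and 5' control signals (horizontal axis) on each of the 21 arrays; points are arrays, open for untreated, and the dotted line marks a log2 ratio of 0.9. The 4 untreated arrays right of the line lie at 52.0 or below and the other 4 at 1057 or above.

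ATRA all times vs ATRA controls set cells given the retinoid for 24hr to 5d against untreated cells of 0hr and 5d. Genes of mature neutrophils, of lysosomes and of the retinoid response rose, and genes of the nucleolar and MYC list and of the S phase list fell. SLC2A5, a fructose transporter, rose by 3.83 (SE 0.23) on the log2 scale, a 14.2-fold change. ORM1, an acute phase plasma protein, rose at least 11.1-fold (log2 3.48, SE 0.10), since all 3 controls lay at the floor. VIM, the intermediate filament vimentin, fell by 3.22 (SE 0.27). All 6 treated arrays lay beyond all 3 controls for each of these genes, as the rule that chose them required. In limma 358 of 3301 genes passed the adjusted p threshold, 171 higher and 187 lower.

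The other leading risers were SLA, NCF1C, FGR, RAB31, FBP1, CFP, CD38 and HIC1, with log2 changes from 2.51 for HIC1 to 3.34 for SLA. NCF1C is the annotation of a probe set, and whether it detects NCF1, a subunit of the phagocyte oxidase, was not tested. CD38, a surface enzyme used as a marker of the retinoid response, rose at least 5.82-fold and HIC1 at least 5.71-fold. The leading fallers after VIM were LGALS1 (log2 -2.21, SE 0.40), FUT7 (-2.15, SE 0.23), PRDX1 (-1.94, SE 0.17), HSPB1 (-1.64, SE 0.44), C1QBP (-1.61, SE 0.27), CAD (-1.59, SE 0.28) and CD99 (-1.56, SE 0.30). MPO, a granule peroxidase of myeloid precursors, was at -0.16 (SE 0.19), MYC at -1.05 (SE 0.83), CD14 at -0.74 (SE 0.53), ITGAM at 0.52 (SE 0.17) and CXCL8 at 0.48 (SE 0.34), and none of these passed the test. Another MPO probe set was at 1.26 (SE 0.95), another ITGB2 probe set at 0.50 (SE 0.27) and another MYC probe set at -1.66 (SE 0.30). EGR1, CDKN1A and SPP1 lay at the floor on every ATRA-arm array.

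Of 21 neutrophil maturation genes, 10 rose and 0 fell (camera adjusted p = 2.09e-09), and 14 rose adjusted over the list alone. CYBB, the catalytic subunit of the phagocyte oxidase, rose by 1.86 (SE 0.17), ITGB2, an integrin chain, by 1.53 (SE 0.17) and S100A8 by 1.17 (SE 0.17). Of 35 lysosome genes, 13 rose and 0 fell (camera adjusted p = 1.57e-10; 18 adjusted over the list alone), with CTSD at 2.26 (SE 0.34) and NPC2 at 1.83 (SE 0.13). Of 19 retinoid response genes, 7 rose (camera adjusted p = 7.76e-06; 7 adjusted over the list alone), among them FGR and CD38. Among 42 adhesion and cytoskeleton genes, 6 rose and 1 fell (camera adjusted p = 0.00136; 9 and 2 adjusted over the list alone). ITGB7 rose and VIM fell.

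Of 39 nucleolar and MYC genes, 17 fell and 0 rose (camera adjusted p = 9.64e-12; 23 adjusted over the list alone), with C1QBP, CAD and NOLC1, a nucleolar phosphoprotein, in the lead. Of 38 S phase genes, 5 fell (camera adjusted p = 0.000955; 5 adjusted over the list alone), with DTYMK at -1.56 (SE 0.33) and POLD2, a DNA polymerase subunit, at -1.51 (SE 0.25). The progenitor list had 2 of 10 members lower, MYB and CD99 (camera adjusted p = 0.0155; 6 adjusted over the list alone). With an estimated correlation its call was lost, at an adjusted p = 0.0961. The other called lists held with an estimated correlation. Without the 9 arrays with bright mismatch controls the S phase, progenitor and adhesion and cytoskeleton lists were not called, and in the values as deposited the last was not. The study signature had 1 of 4 measured members higher, ORM1 (camera adjusted p = 0.0589, and 1 adjusted over the list alone). It was written from memory and may have been chosen by the study in part on such arrays, which the sources used here do not state. It is therefore not taken as independent evidence.

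The ATRA count depended on the untreated arrays: it was 235 without 0hr control 0 and 230 without 0hr control 1, both 3'-biased. Without the 5 arrays with 3' bias, which leaves 1 ATRA-arm control, 165 genes were called, 115 of them shared with the 358. In that fit LGALS1 (log2 -2.51), HSPB1 (-2.03), C1QBP (-1.58), CAD (-1.76), CD99 (-1.24), S100A8 (0.74), NOLC1 (-0.89), DTYMK (-1.14) and MYB (-0.64) were not called, while MYC (-2.13) and CD14 (-2.83) were called lower. HSPB1 was also not called without 0hr control 0 (-1.67) or 0hr control 1 (-1.72). The 7 lists called above were still called by camera. With a common 75th percentile 429 genes were called, 135 higher and 294 lower, a different balance from 171 and 187. With the quantile target over all arrays, the literal reading of the plan, 219 genes were called, 107 higher and 112 lower.

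At ATRA 24hr vs ATRA controls, SLC2A5 (log2 3.58, SE 0.30), NCF1C (3.06, SE 0.26), FBP1 (2.94, SE 0.38) and SLA (2.67, SE 0.40) rose most. VIM (-2.53, SE 0.35), SLC39A14 (at least 2.30-fold lower), P2RY2 (-1.03, SE 0.21) and STMN1 (-0.94, SE 0.19) fell most. In limma 46 genes passed, 39 higher and 7 lower, against 26 and 1 with a quantile target over all arrays. Without the 5 arrays with 3' bias, which leaves 1 treated and 1 untreated array, 27 were higher and 22 lower, and 14 of these 49 were among the 46. Without array 0 of this group 116 genes were called, from the single array with the strongest 3' bias. The cholesterol synthesis list was lower (camera adjusted p = 0.0301, 0 of 15 members called, 0 adjusted over the list alone) and lost its call, at an adjusted p = 0.289 with an estimated correlation.

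At ATRA 3d vs ATRA controls, 223 genes passed, 112 higher and 111 lower (99 and 218 with a common 75th percentile). ORM1 rose at least 14.3-fold, while LGALS1 (log2 -3.22, SE 0.52), FUT7 (-2.65, SE 0.29) and PRDX1 (-2.27, SE 0.22) fell. The count was 92 without array 0 of this group, 133 without array 1 and 137 without 0hr control 1. The progenitor list was lower (1 of 10 called, 1 adjusted over the list alone; camera adjusted p = 0.0448), and lost its call at an adjusted p = 0.157 with an estimated correlation. At ATRA 5d vs ATRA controls, 511 genes passed, 252 higher and 259 lower (200 and 373 with a common 75th percentile). SLC2A5 rose 19.2-fold and ORM1 at least 16.8-fold. CTSG, a serine protease of primary granules, fell by 2.94 (SE 0.33), and TRAP1, a mitochondrial chaperone, by 2.80 (SE 0.25). The count was 312 without array 1 of this group, and 320 with array 0 grouped as 3d. The progenitor list had 4 of 10 members lower (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0121), with an adjusted p = 0.0846 with an estimated correlation. In the direct contrast of 5d with 24hr, 240 genes passed, 116 higher and 124 lower (95 and 174 with a common 75th percentile): CEACAM1 rose at least 6.25-fold and DUSP6 by 2.60 (SE 0.29), while ELANE fell by 2.32 (SE 0.39) and PRTN3 by 2.06 (SE 0.34). That count was 100 without ATRA 24hr array 1 and 137 without ATRA 5d array 1.

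**Figure D2:**
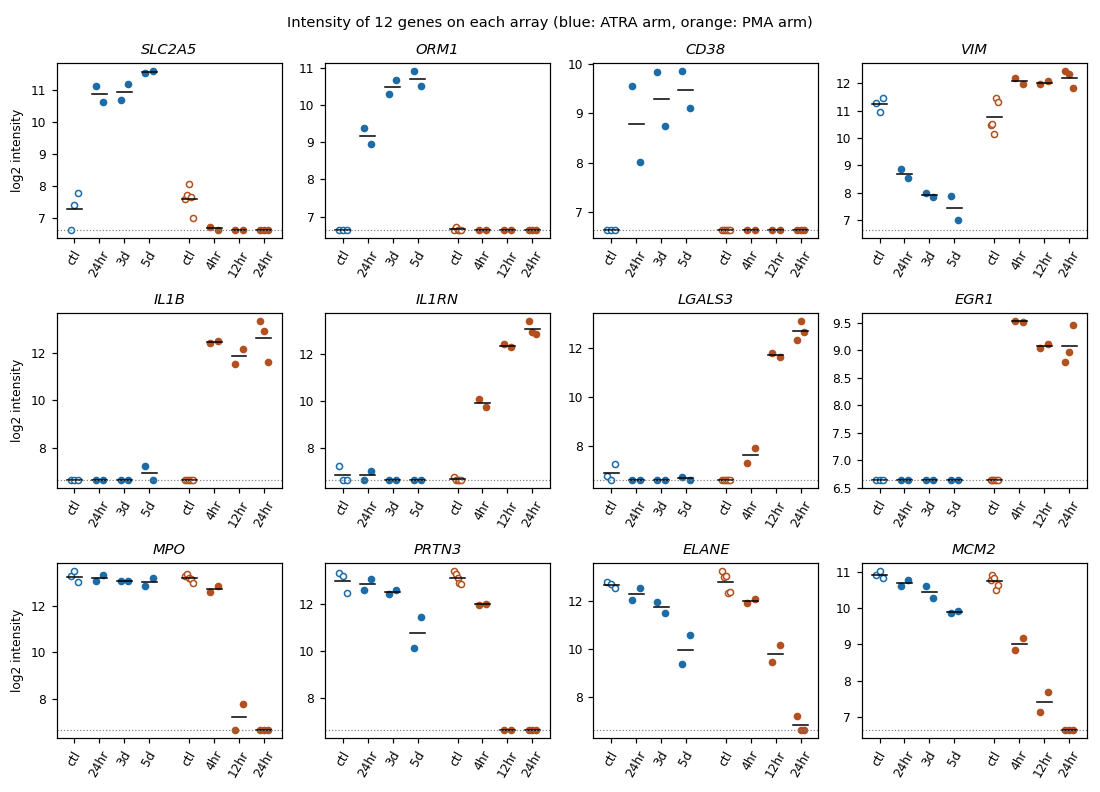
Log2 intensity (vertical axis) of 12 genes on each of the 21 arrays by arm and time (horizontal axis); points are arrays, open for controls, black bars are group means and the dotted line is the floor. SLC2A5, ORM1 and CD38 are high on the ATRA-treated arrays, and IL1B, IL1RN, LGALS3 and EGR1 on the PMA-treated arrays. The MPO probe set shown lies at the floor on all 3 PMA 24hr arrays, while another one lay above the floor on all 21 arrays.

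PMA all times vs PMA controls set cells given the phorbol ester for 4hr to 24hr against untreated cells of 0hr and 24hr. Cytokine genes, immediate early genes and macrophage genes rose, and genes of primary granules, DNA replication and mitosis fell. IL1B, an inflammatory cytokine, rose at least 51.1-fold (log2 5.67, SE 0.22), with all 5 controls at the floor. IL1RN, its receptor antagonist, rose 34.8-fold (log2 5.12, SE 0.12). MPO fell by 4.34 (SE 0.15) and PRTN3, a granule protease, fell by 4.68 (SE 0.20). All 7 treated arrays lay beyond all 5 controls for each of these genes, by the same rule of choice. In limma 1052 of 3301 genes passed, 490 higher and 562 lower.

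The other leading risers were IER3 (at least 41.6-fold), DUSP2 (at least 29.5-fold), CCL4 (at least 27.9-fold), CSF1 (24.1-fold), CCL1 (log2 at least 4.17), LGALS3 (at least 16.4-fold), CXCL8 (13.0-fold) and HBEGF (at least 11.1-fold). Another CCL4 probe set, above the floor on 8 arrays, was at 3.09 (SE 0.19), and a further one, above the floor on 18 arrays, was at -0.03 (SE 0.20). The leading fallers after MPO and PRTN3 were PTPRCAP (log2 -3.35, SE 0.23), ELANE (-3.26, SE 0.23), CTSG (-3.19, SE 0.21), MCM2 (-3.05, SE 0.10) and MYB (-2.83, SE 0.17). Another ELANE probe set was at -0.80 (SE 0.22) and another MPO probe set at -1.63 (SE 0.80). For CXCL8 another probe set was at 5.51 (SE 0.48), against 3.70 for the one that stands for the gene. FUT7 was at least 7.64-fold lower. MYC fell by 2.75 (SE 0.70), EGR1 rose by at least 2.58 on the log2 scale, CDKN1A, an inhibitor of cyclin-dependent kinases, at least 7.45-fold and ITGAM at least 2.89-fold. CD14 (-0.55, SE 0.44) and ORM1 (-0.01, SE 0.09) did not pass, and CD38 lay at the floor on every PMA-arm array.

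Of 33 NF-kB and cytokine genes, 24 rose and 0 fell (camera adjusted p = 1.71e-17; 26 adjusted over the list alone). Of 26 immediate early genes, 19 rose and 1 fell (camera adjusted p = 7.54e-13; 20 and 1 adjusted over the list alone), with RGS2 and JUNB, a subunit of the AP-1 factor, at 3.18 (SE 0.17) and 3.10 (SE 0.15). Of 20 monocyte-macrophage genes, 13 rose and 1 fell (camera adjusted p = 1.71e-08; 13 and 1 adjusted over the list alone), with CTSL, a lysosomal protease, higher by at least 3.46 on the log2 scale and CD9 at least 8.14-fold higher. Of 19 retinoid response genes, 7 rose and 2 fell (camera adjusted p = 0.0018; 7 and 2 adjusted over the list alone). Those that rose include IL1RN, TGFB1, a secreted growth factor, and CRABP2, a retinoic acid binding protein, while CEBPE fell.

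Of 12 primary granule genes, 11 fell (camera adjusted p = 1.22e-09; 11 adjusted over the list alone). Of 38 S phase genes, 23 fell (camera adjusted p = 8.86e-11; 25 adjusted over the list alone), with MCM4 at -2.23 (SE 0.18) and MCM7 at -2.20 (SE 0.22), both subunits of the replicative helicase. Of 36 G2 and mitosis genes, 17 fell (camera adjusted p = 7.24e-05; 17 adjusted over the list alone), and of 39 nucleolar and MYC genes 20 fell (camera adjusted p = 2.92e-06; 22 adjusted over the list alone). Of 20 glycolysis genes, 9 fell and 2 rose (camera adjusted p = 0.0277; 11 and 3 adjusted over the list alone), with PFKL (-2.65, SE 0.40) and PGM1 (-1.66, SE 0.10) lower and SLC2A3, a glucose transporter, at 2.37 (SE 0.37). PFKL was also higher by 1.20 on the untreated arrays with 3' bias. The glycolysis call ended with a filter of 11 arrays (adjusted p = 0.114 by camera) and a floor of 200 (adjusted p = 0.149 by camera), and also without the 5 lower-scale arrays. The retinoid response list was not called in the values as deposited. The 21 neutrophil maturation genes went both ways, 6 higher and 9 lower (camera adjusted p = 0.643; 6 and 9 adjusted over the list alone). ITGAX rose while S100A9, SELPLG and NCF4 fell. The study signature, not taken as independent evidence here either, had IL1RN and SPP1 higher and SRGN lower (camera adjusted p = 0.0709, and 2 and 1 adjusted over the list alone). SRGN was at -0.89 and not called without the arrays with 3' bias. The called lists held with an estimated correlation.

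At PMA 4hr vs PMA controls, CCL4 was at least 78.5-fold and IL1B at least 56.5-fold higher, and PTPRCAP (log2 -3.51, SE 0.32), ZFP36L2 (-2.50, SE 0.27) and PFKL (-2.36, SE 0.57) fell. In limma 447 genes passed, 226 higher and 221 lower. The primary granule list (3 of 12 lower) and the monocyte-macrophage list (5 of 20 higher, 1 lower) were called by camera, at adjusted p = 0.00929 and 0.00886. Both calls were lost, at adjusted p = 0.218 and adjusted p = 0.16 with an estimated correlation. At PMA 12hr vs PMA controls, 781 genes passed, 371 higher and 410 lower, with CCL1 at least 45.7-fold and IL1RN 52.1-fold higher and EPX, an eosinophil peroxidase, at least 13.2-fold lower.

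At PMA 24hr vs PMA controls, 1097 genes passed, 534 higher and 563 lower. CSF1, a macrophage growth factor, rose 72.4-fold and LGALS3 at least 65.7-fold, MPO was at least 94.2-fold and PRTN3 at least 88.3-fold lower, and ELANE fell by 5.98 (SE 0.29). The other MPO probe set lay above the floor on all 21 arrays, so the MPO bound holds for the probe set that stands for the gene. The direct contrast of 24hr with 4hr called 711 genes. CCL5 (log2 5.05, SE 0.26), CRABP2 (at least 30.8-fold) and CD9 were higher at 24hr, and PRG2 was lower (-4.01, SE 0.28). Of 35 lysosome genes, 18 were higher at 24hr than at 4hr and 0 lower (camera adjusted p = 5.67e-08; 18 adjusted over the list alone).

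**Figure D3:**
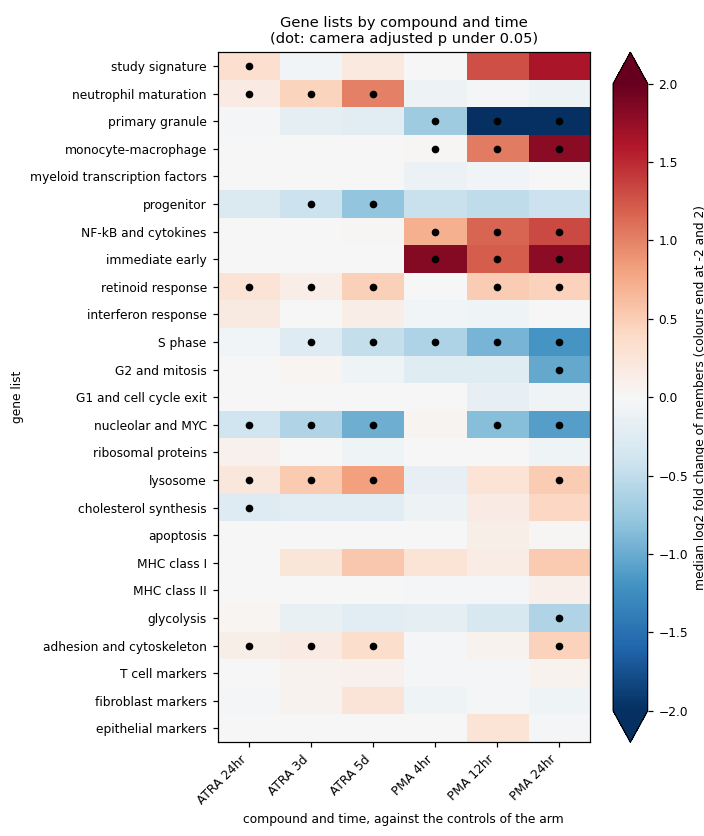
Median log2 fold change of the measured members of each gene list (vertical axis) by compound and time against the controls of the arm (horizontal axis); dots mark a camera adjusted p under the threshold. The nucleolar and MYC list is lower at every ATRA time and at PMA 12hr and 24hr, and the primary granule median reaches -3.77 at PMA 24hr.

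ATRA effect minus PMA effect at 24hr set the compounds side by side at the time they share, at different doses (1 uM and 10 nM). The controls differ in culture time, 0hr and 5d for ATRA and 0hr and 24hr for PMA. In limma 620 genes differed, 311 higher and 309 lower with ATRA. Relative to PMA, MPO, by the probe set that stands for it, was higher by 6.50 (SE 0.31), PRTN3 by 6.31 (SE 0.39), ELANE by 5.60 (SE 0.46) and SLC2A5 by 4.55 (SE 0.38). IL1RN was at -6.42 (SE 0.24), LGALS3 at -6.31 (SE 0.27), CSF1 at -6.18 (SE 0.37) and IL1B at -5.99 (SE 0.44). Several of these genes lie at the floor on some or all arrays of a group, so their sizes hold on the floored scale only. For a difference of 2 effects the floor can shift the size either way. Of 12 primary granule genes, 9 were higher with ATRA (camera adjusted p = 1.09e-11; 10 adjusted over the list alone), and of 33 NF-kB and cytokine genes 17 were lower (camera adjusted p = 1.77e-11; 20 adjusted over the list alone).

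Over all times, 122 genes were lower with both compounds, against 31.8 for independent lists, and 64 were higher with both, against 25.4. FUT7, CTSG, CAD and POLD2 are among the former, BTG1, ITGB7 and FGR among the latter. ITGB2 is also among the latter, but its other probe set was at 0.50 (SE 0.27) with ATRA and 0.22 (SE 0.22) with PMA, so that depends on the probe set. VIM and PRDX1 fell with ATRA and rose with PMA, and SLC2A5, CEBPE and S100A8 did the opposite. The arms share no arrays.

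PMA-arm controls 24hr vs 0hr called 7 genes in limma, 5 higher and 2 lower, at 316 genes with an unadjusted p under the threshold. Of the 0hr controls 2 of 3 are 3'-biased and neither 24hr control is, so culture time is partly confounded with RNA bias here. SDC1 (log2 0.82, SE 0.13), RAB8A and CA8 were higher, and GALK1 and TARBP1 lower. The count was 0 without 0hr control 0 or 0hr control 1, 109 without 0hr control 2, 20 without 24hr control 0 and 1 without 24hr control 1. It was also 0 with the replicate block, the mismatch block and the GAPDH covariate, and 33 without the arrays with 3' bias, 2 of them among the 7. In that fit, with 1 0hr control left, all 7 kept their direction at an unadjusted p under 0.05. ATRA-arm controls vs PMA-arm controls called 0 genes in limma, with 131 at an unadjusted p under the threshold. The count was 1 without ATRA-arm 0hr control 1 or PMA-arm 0hr control 1, 3 without the 5d control and 24 without the arrays with 3' bias.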

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

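The tests of TFRC by loss of 5' ends and by culture time, the test of the overlap by chance and the test of the calls by a fit without the 3'-biased arrays were chosen after the result was seen. The covariates for RNA bias, mismatch signal and deposited scale, the fits without the arrays of bright mismatch controls or of lower scale, and the overlap without the 3'-biased arrays were also added after the data were seen, before their outcome was known.

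The counts of genes called with each compound were set against array properties: with the GAPDH 3'/5' ratio, the bright mismatch class or the deposited scale as a covariate, 100% of the 358 ATRA genes and 100% of the 1052 PMA genes kept their direction at an unadjusted p under 0.05, but this excludes nothing: a covariate built to follow the treatment still kept 65.4% and 57.6%, and shuffled GAPDH ratios kept a median of 100%. In fits without the lower-scale arrays 100% of the ATRA genes and 89.7% of the PMA genes kept it. In the ATRA arm only ATRA 5d array 1 is of lower scale, so the ATRA share had little room to fall. The ATRA comparisons at 24hr and 3d set no lower-scale array against another, which argues against deposited scale as the whole cause of their calls. For PMA, 90.4% kept it without the 3'-biased arrays and 76.3% without those of bright mismatch controls (the bound was 75%). Genes called with all arrays tend to keep their direction in a part of them, so these shares alone decide little. Without the 3'-biased arrays 7 treated and 3 untreated PMA-arm arrays remained. Called afresh on them were 916 genes, of which 795 were among the 1052, which argues against 3' bias as the whole cause for PMA. For ATRA the shares were 72.6% and 69.3%, under that bound, while 357 (99.7%) and all 358 (100%) kept their sign, and without the 3'-biased arrays 97.8%, 89.7% and 81.2% of the genes called at 24hr, 3d and 5d kept their direction at that p. These genes were called with all arrays, and each ATRA fit over all times keeps 5 of the 6 treated arrays and 1 untreated array. No removal of random arrays was run for reference. The signs and shares therefore cannot decide, and RNA bias and mismatch signal both stay open for ATRA. For PMA, mismatch signal and deposited scale stay open.

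Other splits of the same arrays were fitted with 2 groups. For ATRA, 2 of 84 splits called as many genes as the real one, which called 46. The highest other split called 171, several times more, and it set the 3 arrays of the arm with 3' bias against the rest, which points to a structure of the arrays by RNA quality. The ATRA count of the pooled fit without the 3'-biased arrays, given above, comes from a fit of another form and cannot be set against these counts. For PMA over all times, 100 splits were fitted, the real one and others drawn at random. Only the real one reached its count of 749 genes, the highest other being 172. For PMA 24hr, 1 of 56 did so, with 963 genes against 37. Few splits reached these 3 counts, which come from 2-group fits and not from the pooled fit. The ATRA-arm arrays differ by RNA bias, so the share of splits does not exclude an accidental match with that structure there. For the PMA results the shares argue against chance alone. For the controls of the arms, 16 of 56 splits called at least as many genes as the real one, 1 gene, and the highest called 19, so chance is not excluded there.

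The TFRC 3' control signal was low on the 4 untreated arrays with 3' bias, all below the floor, with a mean of 42.5 against 1214 on the other 4. With signals floored at 100 the smallest gap between the sets was at least 3.40 on the log2 scale, but this restates the pattern that prompted the test, so loss of 5' ends stays open. The 0hr array without bias lay 2.07 above the midpoint of the floored signals, but that rests on this single array, so culture time stays open. The median of 9 short-lived transcripts, MYC and immediate early genes, lay at the 85.9th percentile of 10000 matched sets (85.85). That argues against a general loss of this set before lysis. The biased arrays are all from 0hr and most of the others are later. Culture time is thus mixed into this contrast, and a loss of short-lived transcripts is not excluded. The RNA handling of these arrays stays open.

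Genes lower with both compounds numbered 122. Of these, 14 were also called higher on the 3'-biased untreated arrays, the direction that shared bias would give. That is a larger share than the 124 so called among all 3301 genes. Fisher's exact test, one-sided, gave p = 1.11e-52 against independent lists, but it treats genes as independent, and the untreated groups of both arms hold 3'-biased arrays. Without these arrays 44 genes were lower with both, against 12.4 for independent lists (Fisher's exact test, one-sided p = 2.31e-16), which argues against shared 3' bias as the whole cause. The nucleolar and MYC and S phase lists together held 14.8% of the 122 (18 genes), against 2.30% of all genes. With 39 and 38 members they could hardly hold most of the 122, so this cannot tell what share has these functions. Of the nucleolar and MYC list 14 of 39 members were lower with both (Fisher's exact test, p adjusted over the lists = 7.26e-10). For the S phase list it was 5 of 38 (Fisher's exact test, adjusted p = 0.0999). What the remaining genes share stays open. So does the part of 3' bias, since not all of the 44 are among the 122 and the fit without the biased arrays leaves 1 ATRA-arm control.

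Among untreated PMA-arm arrays, 13 tests for a sample far from the others found IL1RN (gap over range 0.883, 0hr control 0), CSF1 (1, 0hr control 1) and FUT7 (0.713, 0hr control 0). Chance alone marks about 1 in 20, but that rate does not hold for CSF1 and IL1RN, where 4 and 3 of the 5 values are tied at the floor.

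The ATRA and PMA effects at 24hr differed, by the test of the difference, in 8 lists. Median differences were 3.73 for primary granule, -1.67 for monocyte-macrophage, -1.03 for NF-kB and cytokines, -1.71 for immediate early, 0.95 for S phase, 1.14 for G2 and mitosis, 0.78 for nucleolar and MYC and 0.87 for glycolysis. The glycolysis call was lost without the arrays with bright mismatch controls. Single genes that differed most were MPO (6.50), PRTN3 (6.31), ELANE (5.60), SLC2A5 (4.55), IL1RN (-6.42), LGALS3 (-6.31), CSF1 (-6.18) and IL1B (-5.99).

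The 18S rRNA control probe set, outside the comparisons, lay above the floor on ATRA-arm 0hr control 0 (233), ATRA 24hr array 1 (494), PMA-arm 0hr control 0 (173) and PMA 4hr array 1 (211).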

How the results depend on the processing

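The GAPDH covariate, the blocks for mismatch class and deposited scale, and the fits without 3'-biased, bright-mismatch or lower-scale arrays were chosen after seeing the data. The literal quantile target, over all arrays, follows the wording of the plan. The target from the 5 lower arrays, behind the main counts, was chosen after the scales were seen. Counts are in the order given; the cause was not tested unless stated. With a common 75th percentile and with the mean of probe sets, every count of calls stayed within 1.5 times, but at the common percentile ATRA calls split 135 higher and 294 lower over all times, 99 and 218 at 3d, 200 and 373 at 5d, and 95 and 174 for 5d against 24hr.

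Values as deposited, which mix scales, gave 0, 1, 3 and 2 genes for ATRA over all times, 24hr, 3d and 5d, 125, 11, 29 and 146 for PMA over all times, 4hr, 12hr and 24hr, 4 for the difference at 24hr, 1 and 10 for the contrasts between times, and 0 for PMA controls by time. The PMA split over all times was 38 higher and 87 lower, and the median of all genes moved by up to -0.86, for ATRA 5d vs ATRA 24hr. Among named genes called in the main fit or in that one, those that reversed sign were IFI35 in ATRA all times vs ATRA controls (-1.53), WARS1 in ATRA all times vs ATRA controls (-0.13) and TARBP1 in PMA-arm controls 24hr vs 0hr (0.58). Sign changes of genes called in neither fit, such as ACTB with ATRA, are not counted. Of the values of named genes, 73 kept their call status there and 158 lost the call. Call status was kept by genes called in the same direction in both fits, or called in neither whatever the sign. The numbers were 227 and 6 at the common percentile, 185 and 47 without 3'-biased arrays, 170 and 58 without bright-mismatch arrays and 204 and 29 without lower-scale arrays. Each arm alone and the target over all arrays lost 32 each and a floor of 20 lost 29. Of the list calls in the 2 main comparisons and the difference at 24hr, 4 were lost without bright-mismatch arrays (glycolysis in the difference among them), 2 as deposited and 1 each without lower-scale arrays, with the filter of 11 arrays, with a floor of 200 and with an estimated correlation.

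For ATRA over all times, 3d and 5d against 24hr, a floor of 20 gave 232, 127 and 91, and each arm alone gave 192, 126 and 81, with 28 at 24hr. The target over all arrays gave 219, 104 and 69, with 27 at 24hr (26 higher, 1 lower). No filter gave 139 at 3d and 137 for 5d against 24hr. Array weights gave 514 and 121, and the GAPDH covariate 143 for the latter. With ATRA 5d array 0 as 3d, 3d had 380, 5d 320 and the contrast 127. The single 5d control gave 286 at 5d. Without 3'-biased arrays, which leaves fewer arrays, ATRA gave 165, 49 at 24hr, 142 at 3d, 328 at 5d and 128 for 5d against 24hr. ATRA-arm against PMA-arm controls gave 24 there and 1 at a floor of 200. Without the 9 bright-mismatch arrays, ATRA gave 119, 79 at 24hr, 88 at 3d and 203 at 5d, PMA gave 635, 193 at 4hr, 577 at 24hr and 374 for 24hr against 4hr, the difference at 24hr 356, and the controls of the arms 21. Without the 5 lower-scale arrays, ATRA 5d gave 310 and 5d against 24hr 95.

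PMA controls by time gave 0 with a floor of 20, the filter of 11 arrays, the target over all arrays, the GAPDH covariate, the mismatch block and without lower-scale arrays. They gave 2 with a floor of 200, 4 with trend and robust moderation, 350 with array weights, 1 with the scale block and 33 without 3'-biased arrays.

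Replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.18 to 0.08 in the ATRA arm and -0.26 to 0.24 in the PMA arm. With a replicate block ATRA over all times had 321 genes, PMA 1006 and PMA controls by time 0.

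Leaving out each array gave 230 to 356 for ATRA over all times, 34 to 116 at 24hr, 92 to 240 at 3d, 312 to 532 at 5d and 100 to 350 for 5d against 24hr. It gave 922 to 1041 for PMA over all times, 300 to 456 at 4hr, 587 to 786 at 12hr, 966 to 1081 at 24hr, 497 to 621 for the difference at 24hr, 0 to 109 for PMA controls by time and 0 to 3 between arms. A lone array left in a group is assumed to vary like the others. Signal over background limits what can be seen: 33.2% of all values lay above the floor.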

Other observations

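The test of biased against other untreated arrays and the fit without biased arrays were chosen after the data were seen. Between the 4 untreated arrays with 3' bias and the other 4, with the arm in the fit, limma called 255 genes, 124 higher and 131 lower on the biased arrays. All 4 biased arrays are from 0hr and 3 of the other 4 from 24hr or 5d, so these calls mix RNA bias with culture time. MYC was lower by 2.69 (SE 0.40), PCNA, a replication clamp, at -2.39 (SE 0.33), CEBPA at -2.22 (SE 0.23) and TOP2A at -1.83 (SE 0.16), genes named after their values were seen. COX17 was higher by 1.60 (SE 0.17). A further MYC probe set read 1049, 873, 882 and 1389 on the biased untreated arrays and 1093, 1154, 1806 and 1628 on the others, so the MYC difference depends on the probe set. With ATRA that probe set was at -1.66 (SE 0.30), against -1.05 for the one that stands for the gene.

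The lists not named as called in a main comparison gave these results. With ATRA, camera adjusted p was 0.986 for primary granule (2 higher, 3 lower of 12; 3 and 3 adjusted over the list alone), 0.332 for monocyte-macrophage (4 and 1 of 20) and for NF-kB and cytokines (2 and 1 of 33), 0.866 for myeloid transcription factors (1 and 1 of 18), 0.305 for immediate early (2 and 0 of 26), 0.0783 for interferon response (4 and 0 of 29), 0.632 for G2 and mitosis (0 and 3 of 36), 0.537 for G1 and cell cycle exit (2 and 2 of 18; 4 and 2 adjusted over the list alone), 0.179 for cholesterol synthesis (0 and 1 of 15), and 0.986 for ribosomal proteins (0 of 42), apoptosis (1 and 1 of 22), MHC class II (0 and 1 of 8) and glycolysis (3 and 4 of 20; 5 and 6 adjusted over the list alone). Where no second count is given, here and for PMA, the count adjusted over the list alone was equal. Without the arrays with 3' bias camera called the cholesterol synthesis list, but that fit leaves 1 ATRA-arm control, the untreated 5d array. The list was also higher in that array than in the 0hr controls, so the call cannot be read as an effect of ATRA. With all arrays, camera adjusted p was 0.457 for MHC class I, 0.626 for T cell markers, 0.537 for fibroblast markers and 0.986 for epithelial markers, with 0 members called.

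With PMA, camera adjusted p was 0.905 for myeloid transcription factors (5 higher, 7 lower), 0.0541 for progenitor (0 and 5; 1 and 5 adjusted over the list alone), 0.713 for interferon response (2 and 7; 2 and 6 adjusted over the list alone), 0.861 for G1 and cell cycle exit (4 and 3), 0.589 for ribosomal proteins (0 and 2; 0 and 1 adjusted over the list alone) and cholesterol synthesis (4 and 1), 0.0683 for lysosome (14 and 5; 14 and 6 adjusted over the list alone), 0.713 for apoptosis (4 and 2) and 0.0761 for adhesion and cytoskeleton (15 and 7; 16 and 9 adjusted over the list alone). MHC class I was at 0.704, MHC class II at 0.713, T cell markers at 0.936, fibroblast markers at 0.951 and epithelial markers at 0.945, with 0 members called. Of the B cell markers CD22 and IGHM, the erythroid marker EPOR and the megakaryocyte markers ITGA2B and TBXAS1, TBXAS1 alone passed in a main comparison, at 1.07 (SE 0.22) with ATRA.

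In the single untreated 5d array of the ATRA arm against its 0hr controls, the cholesterol synthesis list had higher values (camera adjusted p = 2.77e-05; adjusted p = 0.0104 with an estimated correlation), with 0 of 15 members called over all genes and 7 adjusted over the list alone. Only 1 array stands on one side, its spread is taken from the other groups, and both 0hr controls are 3'-biased while it is not, so this is no evidence of a change with culture time.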
